A study of Citrus sinensis with 2 samples.

How the data were processed

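The data were 2 tables of small RNA sequences from pericarp of the Newhall sweet orange at 210 days after bloom, 1 per library. Per the labels' protocols, total RNA was size-selected on a gel for 14 to 30 nt, and libraries were made with the NEBNext small RNA kit for Illumina sequencing. Trimmomatic and BWA 0.7.17-r1188 are named in the submitters' processing notes, without their order or use, and a version of Trimmomatic is not given in the sources used here. The authors deposited raw counts, not normalized, with 1 line per distinct read sequence of 15 to 60 nt. Identical reads had thus been collapsed. Whether reads were filtered by alignment before collapsing is not given in the sources used here, nor is a genome build. Length trimming and any such filter decide which reads enter every share below.

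The replicate numbers of the labels named the libraries, and both belonged to 1 group. Counts were divided by the library's total and given per total reads, scaled to RPM, or as percent. Values are means with the SD over the 2 libraries. Shares of single libraries have exact Clopper-Pearson 95% intervals, which cover counting error only. With 77619816 and 93440634 reads, the limit that a count of 0 allows (3 counts) was 0.0386 and 0.0321 RPM. The main comparisons, the list of 31 miRNA and trans-acting siRNA families (36 sequences, written as DNA) and the alternatives were set before the data were seen, except those named as added. Added after the data were seen were the structural RNA classes built from contigs, the exact binomial test per sequence, the split of agreement by length, and the steps on virus, overlap and last base. Named in the text were families with at least 10 RPM in both libraries and the 3 sequences of highest mean RPM of each of the 21, 22 and 24 nt classes, within the top 10 of each class. Exceptions are said to be such.

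No genome was used. Positions, 24 nt siRNA clusters, siRNAs around gene lists, distribution over the genome and multiple mapping were therefore not analysed here. Structural RNA was found with contigs built from the reads. Each of 39 short parts of ribosomal, transfer, small nuclear and nucleolar RNAs, typed from general knowledge and not taken from a supplied reference, was extended base by base with the most frequent next base among reads of at least 26 nt with at least 3 counts over both libraries (k-mers of 23 nt, at least 20 counts per step, a stop where coverage fell below 0.003 of its running median). The 25S contig reached 3400 nt and the 18S contig 1809 nt. Others grew little or not at all: the chloroplast 23S contig ended at 256 nt, and that of tRNA-Lys stayed at 25 nt. The classes were thus not covered to the same extent. A read was assigned to the class of a contig that held it exactly on the same strand, without its last base where the read was shorter than 60 nt. Reads with adapter sequence (0.215% and 0.307%) were set apart.

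miRNA families were counted by exact match of the listed sequence. Alternatives were sequences of 19 to 24 nt with the same first 18 bases, the same length with up to 2 mismatches (nearest family, ties left out), and a match without the last base, which was added after the data were seen. For the comparison of the libraries, Pearson and Spearman correlations of log2(RPM + 1) were taken across sequences, and sequences with at least 100 counts over both were tested with an exact binomial test of their split against the totals, with Benjamini-Hochberg adjustment. On simulated counts of 131259 sequences with 200 changed and counting error only, that test called 80% of 2-fold and 100% of 4-fold changes, and 5 of the unchanged sequences. The simulation has no spread between libraries beyond counting error, so it does not give the false calls to be met in real libraries. Neither its calls nor the chi-square planned for the same sequences is used here, because a test against counting error alone does not measure agreement. Other alternatives counted distinct sequences once, left out sequences read once, kept 18 to 28 nt, left out the 10 most abundant sequences, thinned the deeper library, or used a pseudocount of 0.1. Those added after the data were seen left out structural RNA contigs, sequences above 100 RPM, or library-specific sequences. The last were defined as at least 100 counts over both libraries and at least 32 times the RPM of the other library, with 3 counts in place of a lower count.

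Contigs of 20 to 22 nt reads (k-mers of 17 nt) were searched with tblastn of BLAST+ 2.17.0 (e-value 0.001) for the coat protein of citrus tristeza virus. That peptide, and a 24 nt probe for fungal 5.8S ribosomal RNA, were typed from general knowledge and not checked against a reference. Pairs of sequences on opposite strands were counted by the overlap of their 5' parts among distinct sequences with at least 2 counts. The last base of reads of 18 to 38 nt was compared with the base that follows the rest of the read in the nuclear ribosomal RNA contigs. On simulated data, the last-base step gave 9.77% where 10% of reads differed, the contig step returned 1498 nt of an RNA of 1500 nt, and the overlap step found the 19 nt put in. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.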

Results

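Small RNA was sequenced from the pericarp, the peel of the fruit, of the navel orange Newhall at 210 days after bloom. The 2 libraries, called library 1 and library 2 after their replicate numbers, form 1 group, so no stage or tissue could be compared with another. The comparisons were between size classes within a library and between the 2 libraries. The title of the series concerns DNA methylation in ripening sweet orange, which makes the 24 nt small interfering RNAs (siRNAs) of interest, since these guide RNA-directed DNA methylation in plants. Library 1 held 77619816 reads of 12611734 distinct sequences, and library 2 held 93440634 reads of 16480549 distinct sequences. Sequences read a single time made up 79.2% of the distinct sequences of library 1 and 77.4% of those of library 2, but 12.9% and 13.7% of the reads. The labels do not say whether the libraries came from separate trees or fruits, so each SD below measures a spread that may be technical.

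The small RNAs formed main peaks at 21 to 22 nt and at 24 nt. A smaller peak lay at 16 nt in library 1, with 7.11% of its reads, against 3.57% at that length in library 2. Reads of 21 nt were the largest class, with 14.1% ± 1.21 of all reads (SD, n = 2), followed by 22 nt with 12.9% ± 0.236 and 24 nt with 10.4% ± 0.900. Reads of 23 nt made up 5.44% ± 0.153. The other lengths together held 57.1% ± 0.395 of the reads. Reads of 15 to 20 nt made up 30.7% ± 6.31 of all reads, and reads of 25 to 31 nt 17.4% ± 0.765 of all reads. Counted as distinct sequences, 24 nt was the largest class, with 21.3% ± 2.46 of the sequences against 10.2% ± 0.0449 for 21 nt. A 24 nt sequence was read 2.94 times on average in library 1 and 2.83 times in library 2, and a 21 nt sequence 8.06 and 8.33 times. Reads of 60 nt, the longest in the files, made up 0.897% of library 1 (Clopper-Pearson 95% interval 0.895% to 0.899%) and 5.83% of library 2. Intervals at this depth are narrow and cover counting error only, because reads copied by PCR are not independent molecules.

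**Figure D1:**
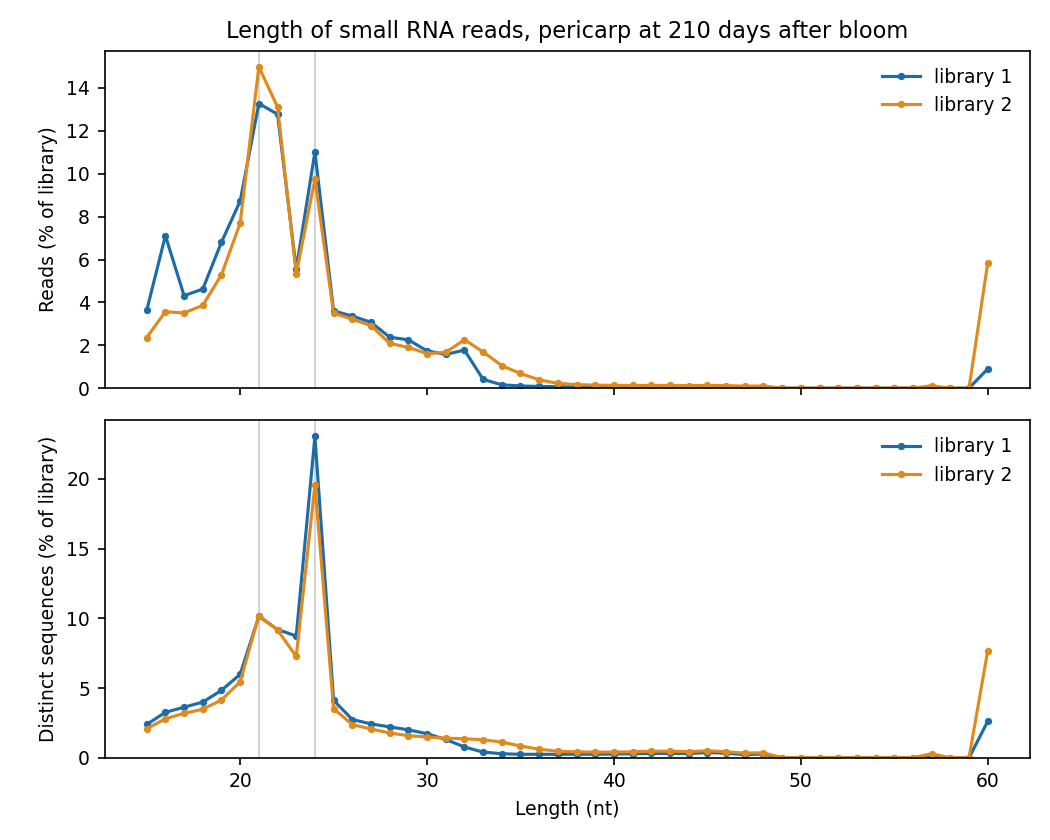
Share of reads (upper panel) and of distinct sequences (lower panel) in percent of each library against read length in nt, with 1 line per library and vertical lines at 21 and 24 nt. The largest class of reads is 21 nt (14.1% on average), and the largest class of distinct sequences is 24 nt (21.3% on average).

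Fragments of ribosomal RNA made up a large part of both libraries. Nuclear ribosomal RNA took 41.5% of the reads of library 1 and 40.5% of those of library 2, by match to contigs of the 18S, 5.8S, 25S and 5S RNAs extended from the reads themselves. Transfer RNA took 6.22% and 2.81%, organellar ribosomal RNA 0.742% and 0.644%, and small nuclear and nucleolar RNA 0.0587% and 0.0161%. Structural RNA contigs took 67.0% ± 2.11 of the reads of 25 to 31 nt and smaller shares of the size classes of Dicer products. These shares were 29.6% ± 8.07 at 21 nt, 25.2% ± 2.44 at 22 nt and 23.6% ± 1.26 at 24 nt, against 46.7% ± 1.29 at 23 nt. All of these are lower bounds, because the contigs hold only part of the structural RNAs, and this way of finding them was chosen after the data were seen.

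Reads of 24 nt were fewer than reads of 21 nt in both libraries. The ratio of 24 nt to 21 nt reads was 0.830 in library 1 (95% interval 0.829 to 0.831) and 0.650 in library 2 (95% interval 0.650 to 0.651), a mean log2 ratio of -0.44 ± 0.25 (SD, n = 2). The direction turned when each distinct sequence was counted once. The ratio of distinct sequences was then 2.27 in library 1 and 1.92 in library 2, a mean log2 ratio of 1.06 ± 0.17. The 24 nt class therefore held more kinds of sequence and fewer reads of each than the 21 nt class. No p-value is given, because 2 libraries are too few for an exact test to reach a small p.

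The first base of a small RNA is known to bias which Argonaute protein takes it up, with U favoured by AGO1 and A by AGO4. Among 24 nt reads, A was the most frequent first base, with 48.8% ± 0.266 (SD, n = 2), and U made up 18.6% ± 0.377. The share of A was 53.1% ± 1.80 among distinct 24 nt sequences. Among 21 nt reads, C opened 34.2% ± 4.19 and U 33.3% ± 0.216, a difference smaller than the SD of C. Without the reads on structural RNA contigs, an alternative chosen after the data were seen, U opened 41.9% and C 26.7% of the 21 nt reads. Among 22 nt reads, A opened 45.4% in library 1 and 33.6% in library 2. A single sequence, AGTTACTAATTCATGATCTGGC, made up 19.9% and 8.82% of that class, and without the 10 most abundant 22 nt sequences of each library A opened 25.3%.

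**Figure D2:**
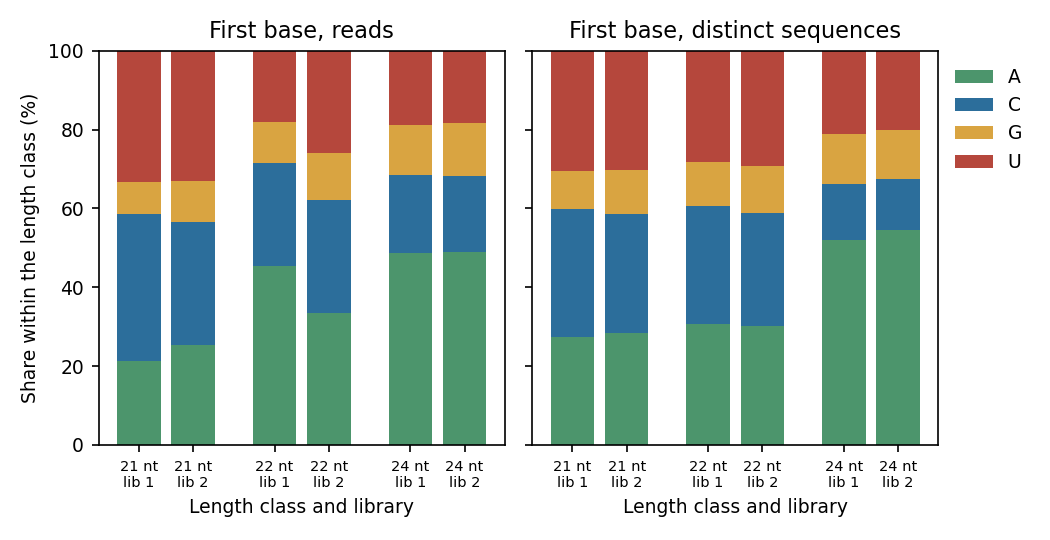
Share of reads (left) and of distinct sequences (right) in percent that begin with A, C, G or U, for the 21, 22 and 24 nt classes of each library (lib 1 and lib 2). A opens 48.8% of the 24 nt reads on average, against 23.3% of the 21 nt reads.

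Of 31 listed families of conserved plant microRNAs (miRNAs) and trans-acting siRNAs, 8 reached at least 10 RPM (reads scaled to the library total) in both libraries by exact match. The most abundant was miR159, which targets GAMYB-like MYB transcription factors, with 657.0 ± 113 RPM (SD, n = 2). It was followed by miR162, which targets the miRNA-processing enzyme DCL1, with 292.6 ± 153 RPM, and by miR166, which targets class III HD-ZIP transcription factors, with 151.8 ± 102 RPM. The order of miR162 and miR166 turned in library 2 (184.5 and 223.7 RPM) and, on average, with length variants (440.7 and 456.6 RPM), with up to 2 mismatches or without the last base. miR482, which targets disease resistance genes of the NBS-LRR type, stood at 86.9 ± 75.4 RPM. miR396, which targets growth-regulating factors, had 74.1 ± 9.36 RPM, and miR164, which targets NAC transcription factors, 71.9 ± 31.7 RPM. The 2 families that target Argonaute genes were lower, with 41.2 ± 0.693 RPM for miR403 (AGO2) and 25.1 ± 15.2 RPM for miR168 (AGO1). The listed families together held 1339 RPM in library 1 and 1552 RPM in library 2, which is 0.134% and 0.155% of the reads.

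The families differed in how far the 2 libraries lay apart. miR403 differed 1.02-fold between them and miR159 1.28-fold, and miR396 had 80.7 RPM in library 1 and 67.5 RPM in library 2. miR166 was 2.80-fold higher and miR482 4.18-fold higher in library 2, whereas miR162 was 2.17-fold higher in library 1. Of the 23 other families, 3 had no read in either library, which allows at most 0.0386 RPM in library 1 and 0.0321 RPM in library 2. Outside the naming rule and chosen after its values were seen, miR408, which targets copper proteins, had 21.9 RPM in library 1 and 1.71 RPM in library 2, a 12.8-fold difference. Exact matching sets a lower bound. With length variants counted, miR167, a regulator of auxin response factors, and miR3954 also passed 10 RPM in both libraries. miR167 rose from 4.55 RPM to 91.9 RPM on average, and also passed with up to 2 mismatches and without the last base. With up to 2 mismatches, miR398 passed as well. Among the families named by the rule, length variants raised miR164 4.13-fold, miR396 3.45-fold and miR166 3.01-fold, and mismatches raised miR482 2.92-fold. miR398, which targets copper superoxide dismutases, rose with mismatches from 0.240 RPM to 177.9 RPM on average, with 305.1 RPM in library 1 and 50.7 RPM in library 2. The direction between the libraries turned with length variants (3.63 and 19.1 RPM) and without the last base (3.48 and 17.8 RPM).

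**Figure D3:**
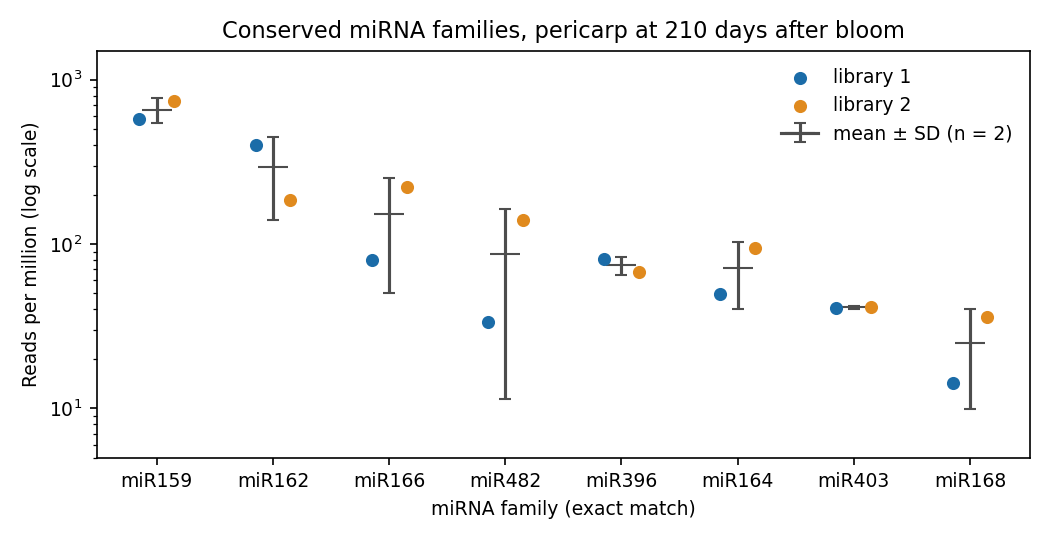
RPM on a log axis for the 8 miRNA families with at least 10 RPM in both libraries, by exact match. Points are the libraries and bars the mean ± SD (n = 2); miR159 is the highest at 657.0 RPM on average, and miR482 ranges from 33.6 to 140.3 RPM.

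A few sequences held a large part of the 21 and 22 nt reads, and apart from miR159 these came from ribosomal RNA or matched no listed RNA. The 10 most abundant sequences of the 22 nt class held 29.3% ± 11.8 of its reads, those of the 21 nt class 19.7% ± 8.69 and those of the 24 nt class 6.81% ± 1.14 (SD, n = 2). At 21 nt the leading sequence was CCCTACGTCGCTCAGATTCGT of 25S rRNA with 10195 ± 4229 RPM, followed by TATCTGGATAAAAGGCTACCC with 5267 ± 2175 RPM and TATCTGGATAAAAGGCTACCT with 2767 ± 952 RPM, which matched no listed RNA. At 22 nt, AGTTACTAATTCATGATCTGGC had 18516 ± 9837 RPM and AGTTACTAATTCATGATCTGGT 5964 ± 2738 RPM, again with no match to a listed RNA. The third was GCCCTACGTCGCTCAGATTCGT of 25S rRNA with 3257 ± 412 RPM. At 24 nt the leading sequences were CAGCCCTACGTCGCTCAGATTCGT of 25S rRNA with 2877 ± 635 RPM and CAAAACGACTCTCGGCAACGGATA of 5.8S rRNA with 1489 ± 221 RPM. AGTTACTAATTCATGATCTGGCAT, an extension of the leading 22 nt sequence, had 762.5 ± 408 RPM. Of the 10 leading sequences, 5 at 21 nt, 7 at 22 nt and 6 at 24 nt matched structural RNA contigs, and 1 at 21 nt was miR159. The 2 unmatched sequences named at 21 nt differ only in their last base, as do the 2 at 22 nt. Each pair may be 1 RNA counted as 2 sequences, which was not tested.

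The 2 libraries shared most of their reads but few of their sequences. Of 26162401 distinct sequences in either library, 2929882 (11.2%) were in both, and these held 85.6% of the reads of library 1 and 74.6% of those of library 2. Across all sequences, log2(RPM + 1) had a Pearson r of 0.82 and a Spearman rho of -0.49. The set took in sequences of either library, and most had reads in only a single library. This construction pulls rho below zero, so its sign does not show that the libraries rank sequences in opposite order. Among the 912244 sequences with at least 10 counts over both libraries, r was 0.79 and rho turned positive, at 0.21. Sequences are not independent replicates, so no p-value belongs to these values. These values compare the libraries, not conditions.

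Agreement, split by length after the data were seen, was by r and by the share over 2-fold poorer for 20, 21, 22 and 60 nt sequences than for 23 nt, 24 nt and 25 to 31 nt sequences. Among sequences with at least 100 counts, 49.4% of the 21 nt sequences and 8779 of 17554 sequences at 22 nt differed over 2-fold between the libraries, against 27.5% at 23 nt, 24.3% at 24 nt and 24.6% at 25 to 31 nt. The SD of the log2 ratio was 4.04 at 21 nt and 3.98 at 22 nt, against 1.77 at 23 nt, 1.07 at 24 nt and 0.99 at 25 to 31 nt. Pearson r across sequences was 0.50 at 21 nt and 0.49 at 22 nt, against 0.85, 0.87 and 0.89 in the longer classes in that order. At 20 nt, 39.2% differed over 2-fold, with an SD of 3.37 and an r of 0.69. At 60 nt, 96.5% did, with an SD of 1.73, an r of 0.59 and a median log2 ratio of 3.95 towards library 2. Library-specific sequences, of which 328 in library 1 and 10917 in library 2 were 20 to 22 nt long, were not left out of this split. Of the sequences outside structural RNA contigs, 51.9% differed over 2-fold, with an SD of 3.79, an r of 0.39 and a Spearman rho of 0.03. For those on the contigs, these values were 27.6%, 1.71, 0.81 and 0.66.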

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

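Of the tests in this part, the protein match and the structural RNA shares of the 20 to 22 nt members and of the members of library 1 were chosen only after the result was seen. Each value of this part is a signal that the planned comparisons did not look for, above the 3 counts that a count of 0 allows, and the series has no control samples. The virus peptide and the fungal probe were typed from general knowledge, so the names of these sources rest on matches that were not checked against a reference.

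Reads matching a plant virus were present in both libraries. Contigs of 20 to 22 nt reads encoded 153 of the 223 residues of the coat protein of citrus tristeza virus in library 1 and 203 in library 2, at 96.2% and 96.7% identity, and 0 residues of the same peptide read backwards. On these contigs lay 160811 reads in library 1 (2072 RPM) and 547377 reads in library 2 (5858 RPM), each on the contigs of its own library. The gap between the libraries depends on the contigs, since library 2 had 2623 RPM on those of library 1, and library 1 had 2228 RPM on those of library 2. Of the reads of each library on its own contigs, 63.2% and 69.1% were 21 or 22 nt long, while 1.39% and 1.07% were 24 nt. Contigs built from 20 to 22 nt reads favour those lengths, and could miss stretches read mainly at 24 nt. The strand with fewer reads held 32.9% and 39.6% of the reads of each library on its own contigs.

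Sequences at least 32-fold higher in 1 library numbered 571 in library 1, with 0.276% of its reads, and 15310 in library 2, with 6.61%, and 68.2% and 71.8% of these reads were 20 to 22 nt. Fragments of the structural RNAs held by the contigs are argued against for the 20 to 22 nt members, of which 0 reads lay on structural RNA contigs. They are also argued against for all members of library 1, where the structural share was 0.00567 times that of the whole library. They stay open for all lengths in library 2, where it was 0.38 times. Structural RNA missing from the contigs, which may include that of other organisms, could not match and stays open throughout. A candidate source in library 2 is the virus, as 28.5% of its coat protein reads lay in library-specific sequences, against 6.61% of all its reads. Of all its 21 and 22 nt reads, 15.9% and 14.0% lay in such sequences. The contigs behind the 28.5% were built from the reads of library 2 itself, which favours sequences abundant there, while the other shares have no such selection. The library-specific reads of library 2 numbered 6173164, of which 155762 were coat protein reads. Only the coat protein was searched for, so this count leaves out other parts of the virus and does not bound its share. In library 1, 0 of the coat protein reads lay in library-specific sequences. How much the virus supplied in library 2, and the source of all in library 1, stay open. Cutting by a Dicer enzyme, which would leave 21 nt pairs with an overlap of 19 nt, may apply in library 2, where that overlap was the most frequent (527 pairs), while in library 1 it was not (11 pairs among 150 sequences). At 22 nt the corresponding overlap of 20 nt was the most frequent in both libraries, with 13 and 426 pairs, so cutting stays open there too.

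A 24 nt sequence typical of fungal 5.8S ribosomal RNA occurred in 65485 reads of library 1 (843.7 RPM) and 157848 reads of library 2 (1689 RPM).

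Reads of 60 nt numbered 696508 in library 1 and 5447462 in library 2, although the protocol selected 14 to 30 nt, and structural RNA contigs held 19.8% and 51.4% of them.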

How the results depend on the processing

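Alternatives that left out structural RNA contigs, library-specific sequences or sequences above 100 RPM, or that ignored the last base, were chosen after the data were seen. Shares are in percent of reads, and a shift counts when it is over 1 SD of the 2 libraries (for correlations, outside the interval for the number of sequences). That interval takes sequences as independent, which they are not, and is so narrow that shifts lost in rounding count too. Unless a construction shows it, the cause was not tested. Distribution over the genome, 24 nt clusters, siRNAs around gene lists, their alternatives, multiple mapping and structural RNA by a reference were not run, for lack of a genome. No paired analysis was possible because there is 1 group. Leaving out either library moved no share, ratio or RPM by more than 1 SD, a shift that 2 libraries cannot exceed, and the log2 ratio of 24 nt to 21 nt reads stayed negative. Without library 1, U came before C at 21 nt (33.1% and 31.2%) and miR166 before miR162.

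The 24 nt to 21 nt ratio reversed with distinct sequences (log2 1.06; 1.11 without their last base). It moved to -0.75 without sequences read once, to -0.11 without sequences above 100 RPM, where library 1 alone turned positive (0.18), and to -0.15 without structural RNA and library-specific sequences, where the ratio was 1.003 in library 1 and 0.813 in library 2. Counting distinct sequences gave 10.2% at 21 nt, 9.18% at 22 nt, 8.001% at 23 nt and 21.3% at 24 nt, and without the last base 9.82%, 8.94%, 8.07% and 21.3%. Over 18 to 28 nt, a smaller total, the shares were 19.3%, 17.6%, 7.41% and 14.1%. Without structural RNA, 21 and 24 nt took 18.5% and 14.8%, and 22 nt 18.1% and 17.9% by library. Without sequences read once, 22, 23 and 24 nt took 13.6%, 5.03% and 8.78%, and without the 10 most abundant 11.2%, 5.92% and 11.3%. Without library-specific sequences, 22 and 23 nt took 12.4% and 5.61%.

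U at 21 nt moved to 30.4% with distinct sequences, 33.6% without those read once, 32.2% without the 10 most abundant and 41.9% without structural RNA, and C to 26.7% in the last. A at 22 nt moved to 30.5% with distinct sequences and 25.3% without the 10 most abundant. A at 24 nt moved to 53.1%, 47.5%, 50.4% and 56.0% in the order given for U. Families above 10 RPM numbered 8 to 10 throughout. The summed RPM of all 31 listed families moved from 1446 to 3375 RPM with length variants, 2281 with up to 2 mismatches, 1871 without the last base and 1972 over 18 to 28 nt, a smaller total.

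Spearman rho across sequences reversed to 0.21 with at least 10 counts over both, was -0.50 after thinning, -0.53 without structural RNA and -0.49 without library-specific sequences. Pearson r was 0.69 with a pseudocount of 0.1, 0.79 with at least 10 counts, and 0.82 after thinning and without the 10 most abundant. It was 0.69 without structural RNA and 0.88 without library-specific sequences. The latter rise follows from the construction, since those sequences were picked for differing between the libraries. Reads in shared sequences moved from 80.1% to 94.98% with at least 10 counts and to 64.0% without structural RNA. Depth limits the rare sequences, since 79.2% and 77.4% of distinct sequences were read once.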

Other observations

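The tests of the last base were chosen only after the result was seen, whereas the predictions for the 24 nt to 21 nt ratio were written before those tests were run. The ribosomal RNA contigs grew from sequences typed from general knowledge. The most abundant 22 nt and 21 nt sequences without a match were each searched for by a core near their start. Reads that held the whole core mostly began at 1 fixed base. Reads that began within or beyond the core were not counted, so the shares leave those starts out. Of 5067377 reads over both libraries with the core of AGTTACTAATTCATGATCTGGC, 96.7% began at the same base, and 7 reads held the opposite strand. For TATCTGGATAAAAGGCTACCC, 96.1% of 1611493 reads did, with 67 on the opposite strand. Among all sequences outside structural RNA, the overlap of opposite strands that marks a Dicer duplex was not the most frequent at 21, 22 or 24 nt in either library. The most frequent was in each case 15 nt, the shortest overlap counted, and pairs mostly became fewer as the overlap grew. This ranking therefore cannot decide whether Dicer duplexes were present. At 24 nt, library 1 had 15397 pairs at the overlap of 22 nt, against 17941 at 21 nt and 15639 at 23 nt.

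The last base of trimmed reads differed from the ribosomal RNA contigs in 17.2% of the reads of library 1 and 18.1% of those of library 2. Sequencing error is argued against, as the rate at the base before the last was 0.0406 and 0.0435 times as high. A remnant of the 3' adapter, which begins with A, is argued against as the whole cause, as A made up 27.0% and 26.3% of the differing bases at templated C. Addition of bases to the RNA's 3' end is argued against as the whole cause, as the odds of A against U were 12.6 and 12.5 times higher at templated G than at templated C. A mixture of these and miscopying of the first base by reverse transcriptase stay open, and the effect may split 1 RNA into several distinct sequences. The counts of the 8 named miRNA families were 1.03-fold (miR168) to 2.45-fold (miR166) higher without the last base. Such a match also takes in family members that end in another base, and the 2 sources were not told apart. At the rates seen in ribosomal RNA, the last-base effect alone is too small for the rise of miR166.

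For the excess of 21 nt over 24 nt reads, library-specific sequences as defined here are argued against as the whole cause, with 24 nt to 21 nt ratios of 0.836 and 0.772 without them. Fragments of structural RNA stay open, since the ratios without them were 0.991 and 0.645, a mean log2 ratio of -0.32 with an SD of 0.44, and the contigs hold only part of these RNAs. Without both, the ratios were 1.003 and 0.813. Sequences above 100 RPM may contribute in library 1, where the ratio without them was 1.13, but in library 2 it was 0.755. No alternative left out the virus reads as such, and their part in the ratio was not tested. Of the coat protein reads of libraries 1 and 2, 36.7% and 42.0% were 21 nt long, against 1.39% and 1.07% of 24 nt. No biological explanation was tested, and what sets the ratio stays open.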
